A study of Mus musculus with 7 samples.

How the data were processed

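Gene counts of 7 RNA-seq libraries of TRAMP-C1 cells were used: 1 library labelled WT, 3 with empty vector and 3 with the PAX8-NFE2L2 fusion. Per the labels' protocols, cells were transduced with concentrated lentivirus made from the Lv229 plasmid, given fresh medium after 12 h and grown for another 24 h, and polyadenylated RNA was sequenced as 50 bp single-end reads on an Illumina HiSeq instrument. The deposited values are whole-number counts of reads per gene, 1 table for each lane of a library, and per the submitters' processing notes the authors used STAR, HTSeq and the genome build GRCm38. Tool versions, the annotation release and the strand setting are not given in the sources used here. Without a known strand setting, reads of genes that overlap on opposite strands cannot be told apart, which concerns 12 of the 60 named genes. Reads that align to more than 1 place stand in a row of their own in the deposited tables and not under a gene, so paralogs can be undercounted.

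The 12 lane tables were read, and lanes of a library were summed. The 2 lanes of a library differed by no more than sampling noise (chi-square per degree of freedom 0.981 to 1.01, p = 0.191 to 0.956) and counted as 1 sample, while libraries of 1 group differed far more (98.8 to 283). Replicates 1 and 2 and the WT library came from lanes 5 and 6, empty vector replicate 3 from lane 1 and fusion replicate 3 from lane 2. Of 46603 gene rows, 46005 had a symbol, and symbols, positions and overlaps come from GENCODE release M21 of GRCm38, in which 65 of the tested genes were not placed. Rows that name no gene stayed out of library sizes and tests: reads outside genes were 5.726 to 6.927% of each library's total, ambiguous reads 1.222 to 1.479% and reads with several alignments 36.1 to 45.32%, highest in the libraries numbered 3. The 92 spike-in control rows held at most 2 counts in a library. Gene counts per library lay between 26368182 and 59597170, 21216 to 22697 genes were detected, and the 10 most abundant genes held 4.809 to 7.528% of the counts. Limits for 0 counts (3 counts) and counting intervals cover counting error only, since the reads carry no molecular identifiers.

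Fusion was compared with empty vector in the 6 libraries of these groups by edgeR 4.0.16 in R 4.3.3, with TMM normalization (factors 0.9815 to 1.027) and filterByExpr with a minimum count of 10. It used robust dispersion estimates (biological coefficient of variation 0.301), the quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05 over 16731 genes. Empty vector was compared with WT, whose treatment the labels do not tell apart from the rest, in the same way over the same genes in all 7 libraries, where the 1 WT library is assumed to vary like the other groups. Both comparisons share the empty vector libraries, so their calls are not compared with each other. CPM use the TMM factors over the 7 libraries (0.944 to 1.037). The log2 fold change of a gene with 0 empty vector counts is not a bound, so its fold is given against 3 counts over the group. For 1 to 3 counts the ratio is given with an exact 95% binomial interval. These folds and ratios pool the counts of a group's libraries, so deeper libraries weigh more than in the mean CPM.

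The groups share replicate numbers in the labels. Deviations from the group means correlated between libraries of the same number (r = 0.535, 0.488 and 0.459 over genes for numbers 1, 2 and 3) and not between different numbers (-0.0497 to -0.427). The numbers were therefore taken to pair the samples. Deviations sum to 0 within a group, so the negative values follow from the positive ones and are no separate evidence. The source of the pairing is this check, as no label names a shared batch or day. In a principal component analysis of the 6 libraries the first component (44.6% of the variance) separated the groups and the second (27.4%) set both libraries numbered 3 apart. The main fit, fixed before the data were examined, leaves this pairing out. The fit with a replicate block uses it and is an alternative.

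Before the data were examined, 29 gene lists, the tests, the rule for named genes and most alternatives were fixed; alternatives and tests added later are named where they appear. The lists are construct genes and NRF2 partners, NRF2 targets, glutathione and thioredoxin, NADPH generation, xenobiotic conjugation and export, iron and heme, ATF4 and amino acid response, unfolded protein response, heat shock response, proteasome, interferon response, class I antigen presentation, and NF-kB and cytokines. The others are cell cycle, p53 targets, cholesterol biosynthesis, fatty acid synthesis, glycolysis and hypoxia, oxidative phosphorylation, mitochondrially encoded genes, cytosolic ribosomal proteins, mesenchymal and matrix, prostate epithelial, neuroendocrine cells, fibroblasts, immune cells, endothelial cells, PAX8-linked thyroid and kidney genes, and growth factor immediate early genes. Some genes stand in more than 1 list. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. They were tested again with an estimated correlation and with fry, which asks whether a list's genes move one way and does not compare them with other genes. Named genes are Pax8, Nfe2l2 and Keap1, the 8 largest rises and 8 largest falls among protein-coding genes past the threshold with a mean of at least 2 CPM and no overlap between groups. From each list the rule adds up to 4 members past the threshold with the smallest p or, where none passed, the most abundant member as a value. The same rule named no gene for empty vector against WT. A gene that the rule names is not reported here. List medians were the same with genes of 0 to 3 empty vector counts set at their bounds or ratios.

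Alternatives were RLE, upper quartile and library size scaling, no filter and a filter of 1 CPM in 3 libraries, DESeq2 1.42.0 and limma-voom. Others were the replicate block, all 7 libraries, 1 lane per library, libraries thinned to the smallest total, a threshold of 0.01, and leaving out each library or each replicate number. The tests were run on simulated counts with 200 changed genes among 16731. For fusion against empty vector 11.9%, 70.1% and 92.4% of genes changed 2-, 4- and 8-fold were recovered and 7.2% of calls were false. With the replicate block these shares were 58.2%, 92.5% and 95.5% and 9.89%, and for empty vector against WT 0%, 43.3% and 80.3% and 6.82%. Of 20 simulated lists the 1 changed list was called and 0 others. Genes were simulated independently of each other, so this run does not test lists whose genes vary together. For the fits without the block, counts were simulated without an effect of the replicate number. Their shares therefore do not describe libraries that pair by number.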

Results

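RNA-seq libraries were made from TRAMP-C1, a mouse prostate epithelial tumour line of the C57BL/6 TRAMP strain, in which a transgene drives prostate tumours. Cells were transduced with a lentivirus carrying a PAX8-NFE2L2 fusion gene or with the matching empty vector, in 3 libraries each. A further library was named WT, with no vector given in its label. PAX8 is a transcription factor of thyroid and kidney development, and NFE2L2 encodes NRF2, the transcription factor that turns on antioxidant and detoxification genes and that KEAP1 marks for degradation. Polyadenylated RNA was sequenced as 50 bp single-end reads after 12 h with virus and 24 h in fresh medium. Reads assigned to genes came to 52859158 in the WT library, and to 59597170, 55088196 and 40089266 in empty vector replicates 1, 2 and 3. They came to 52524828, 55114667 and 26368182 in fusion replicates 1, 2 and 3. At these depths a gene with 0 counts in a library could lie at up to 0.0503 to 0.114 CPM (counts scaled to a library size of 1e+06), counting error only. Levels are given as mean ± SD in CPM over n = 3 libraries, and as 1 value for the WT library, which has no replicate. No label says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

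The construct genes were read first in every library. Pax8 (ENSMUSG00000026976.14, chromosome 2:24420560-24475599, minus strand, GRCm38) lay at 0.04 CPM in the WT library and at 0.0334, 0.0358 and 0.217 CPM in empty vector replicates 1, 2 and 3, against 6.4, 8.54 and 5.58 CPM in fusion replicates 1, 2 and 3. Its log2 fold change was 6.25 (SE 0.65, edgeR quasi-likelihood adjusted p = 0.0033). Nfe2l2 (ENSMUSG00000015839.6, chromosome 2:75675513-75704641) lay at 119 ± 7.15 CPM with empty vector, 136 ± 11.9 CPM with the fusion and 120 CPM in the WT library. Its log2 fold change of 0.19 (95% interval -0.214 to 0.598) did not pass the test (edgeR adjusted p = 0.89). The mean rose by 6.74 CPM for Pax8, and the means of Nfe2l2 lay 17 CPM apart. Keap1 (ENSMUSG00000003308.13, chromosome 9:21229730-21239361) lay at 53.9 ± 4.74 CPM with empty vector, 88.3 ± 7.16 CPM with the fusion and 87 CPM in the WT library. Its log2 fold change of 0.71 did not pass (edgeR adjusted p = 0.12). It passed in the paired fit (adjusted p = 0.0034) and with DESeq2 (adjusted p = 0.0097). Counts per gene do not separate reads of the construct from reads of the cells' own genes, and the species of the construct's sequence is not given in the sources used here. Pax8 and Keap1 each overlap a gene on the other strand, so their reads cannot be assigned with certainty.

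**Figure D1:**
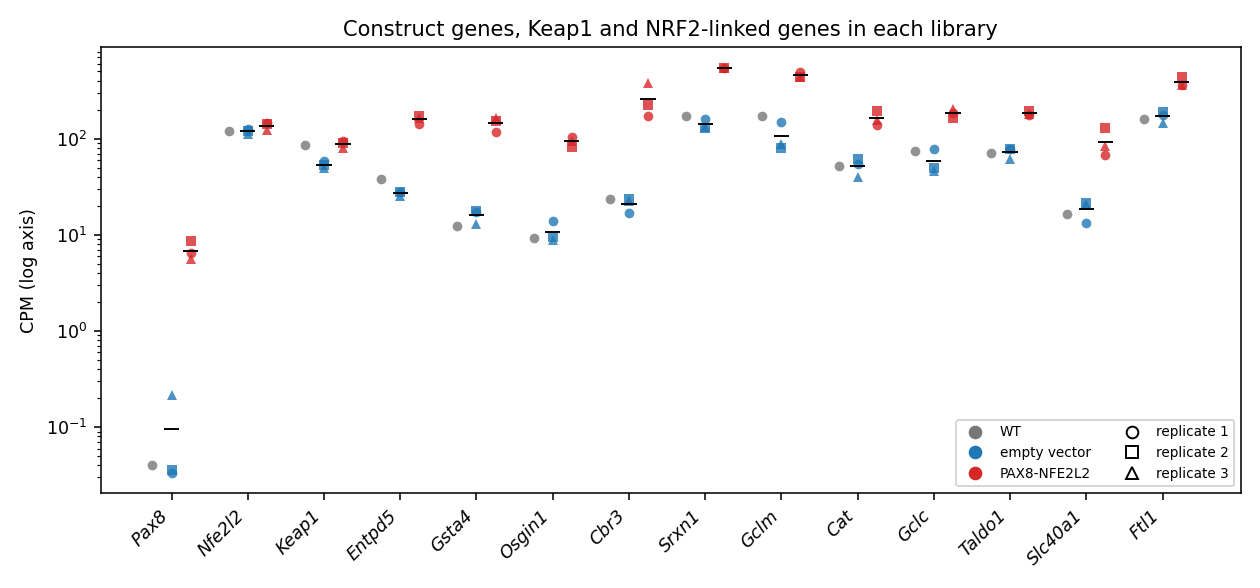
CPM on a log axis of Pax8, Nfe2l2, Keap1 and 11 called genes of the NRF2, glutathione, NADPH and iron lists in each of the 7 libraries. Colour gives the group, the symbol gives the replicate number and black bars are group means; for the 11 called genes every fusion library lies above every empty vector library.

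The comparison that the series was designed for asked what expression of the fusion transcript changed relative to empty vector. With the fusion 282 genes rose and 59 fell among 16731 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Their median log2 fold changes were 2.91 and -2.08. The risers included genes of NRF2 signalling, glutathione synthesis and conjugation of foreign compounds, and the largest falls that the rule for named genes took included Ncam2 and Adcy8. Of the 341 genes, 336 changed at least 2-fold, and in all 341 the 3 fusion libraries lay on one side of the 3 empty vector libraries. Over all tested genes 1532 were higher and 1112 lower in every fusion library than in every empty vector library. Chance would give 5% each way only if the libraries were exchangeable, which their pairing by number goes against, so no expected share is given. Replicate numbers were taken to pair the samples, and the fit with a replicate block called 2196 genes, 1276 higher and 920 lower, among them 340 of the 341. DESeq2 called 922, 622 higher and 300 lower, among them all 341. Both libraries numbered 3 came from other sequencing lanes than the rest. Numbers 1 and 2 alone gave 329 genes, 217 of them among the 341. Without number 1, 36 passed (34 higher, 2 lower), and without number 2, 4 passed (4 higher, 0 lower), all of them among the 341. These fits leave the pairing out. The replicate block was run on these subsets after the data were seen. It called 3200 genes without number 3, 1537 without number 1 and 409 without number 2. Number 3 has 1 library per group, which allows no test. Leaving out empty vector replicate 2 gave 133 genes, fusion replicate 1 gave 196 and fusion replicate 2 gave 148.

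**Figure D2:**
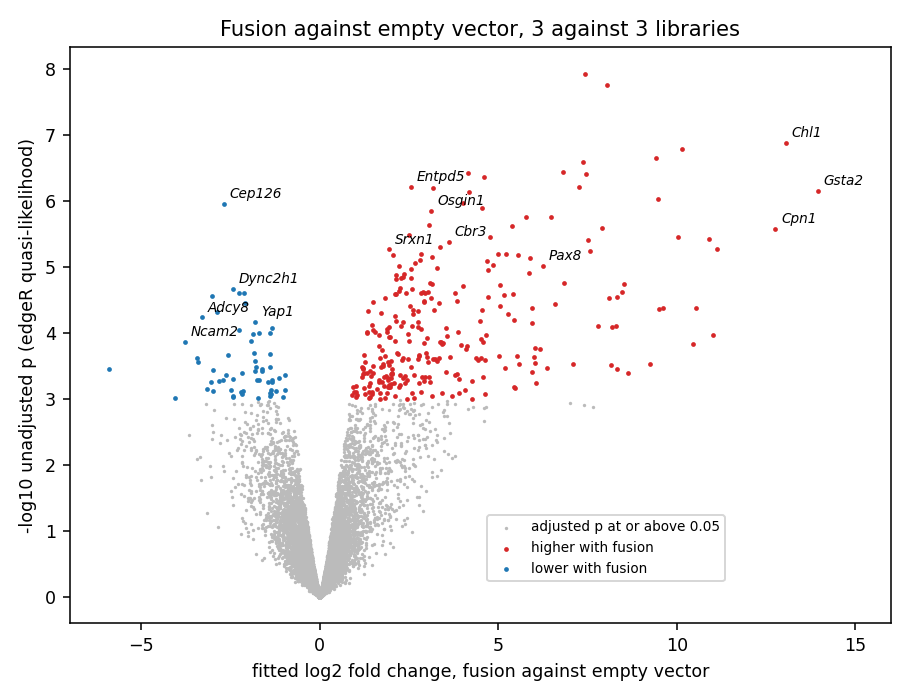
Fitted log2 fold change of fusion against empty vector for 16731 tested genes against the negative log10 of the unadjusted edgeR p, with genes past an adjusted p of 0.05 in red (282 higher) and blue (59 lower) and the rest in grey. Fitted values of genes with almost no empty vector reads, such as Gsta2, depend on the fitting and are no measure of their fold.

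NRF2 target genes rose together. Of 39 measured members of the list 18 rose and 0 fell, 32 and 0 when adjusted over the list alone, with a median log2 fold change of 1.19 (camera adjusted p = 2.9e-58). In the paired fit, with the replicate block, 35 rose and 0 fell. Entpd5, an endoplasmic reticulum nucleotidase, went from 27.1 ± 1.56 to 160 ± 14.9 CPM (log2 fold change 2.56, SE 0.19, edgeR adjusted p = 0.0008). Gsta4, a glutathione transferase that clears lipid peroxidation products, went from 16 ± 2.5 to 145 ± 23.7 CPM (3.18, SE 0.23, 0.0008). Osgin1, an oxidative stress-induced growth inhibitor, went from 10.7 ± 2.78 to 93.7 ± 10.7 CPM (3.13, SE 0.25, 0.0012). Cbr3, a carbonyl reductase, went from 21 ± 3.49 to 258 ± 106 CPM (3.62, SE 0.34, 0.0022). Nqo1 and Hmox1, textbook NRF2 targets chosen here after their values were seen, had log2 fold changes of 2.24 (edgeR adjusted p = 0.0052) and 1.06 (adjusted p = 0.065, not past the threshold, and 0.0040 with the replicate block). Members did not all move: Akr1b8 had a log2 fold change of -0.13 and Trim16 of 0.03, and neither passed, with the replicate block too. The xenobiotic conjugation and export list had 17 of 36 members up and 0 down, 25 and 0 adjusted over the list alone (median 1.44, camera adjusted p = 3.9e-50), and 25 and 0 with the replicate block. It shares members with the NRF2 target list, Gsta4, Cbr3 and Nqo1 among them, so the 2 lists are not independent. These 2 lists kept their calls with an estimated correlation (adjusted p = 0.0261 for each) and lost them when that was combined with the replicate block (adjusted p = 0.262 for NRF2 targets and 0.179 for conjugation and export).

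The lists of antioxidant, NADPH and iron genes had 5, 1 and 2 members that rose, and each of these 3 list calls was lost with an estimated correlation. Srxn1, Gclm, Gclc, Cat, Taldo1 and Ftl1 stand in the NRF2 target list too, so these lists are not independent of it. In the glutathione and thioredoxin list 5 of 30 members rose and 0 fell, 9 and 0 adjusted over the list alone (median 0.44, camera adjusted p = 3.1e-07, 0.147 with an estimated correlation). Its median was 0.21 without fusion replicate 3 and 0.29 without empty vector replicate 2. With the replicate block 14 members rose, and Prdx4, a peroxiredoxin, and Gpx8, a glutathione peroxidase family member, fell (log2 fold changes of -0.56 and -0.64, edgeR adjusted p = 0.019 and 0.044). Srxn1, which repairs peroxiredoxins, went from 141 ± 16.5 to 546 ± 3.64 CPM (log2 fold change 1.95, edgeR adjusted p = 0.0026). Gclm and Gclc are the subunits of the first enzyme of glutathione synthesis. Gclm went from 107 ± 38 to 458 ± 27.2 CPM (2.10, adjusted p = 0.0081) and Gclc from 58.3 ± 17.8 to 184 ± 19.8 CPM (1.66, adjusted p = 0.016). Cat, catalase, went from 51.9 ± 10.8 to 163 ± 29.2 CPM (1.65, adjusted p = 0.012). In the NADPH list 1 of 12 members rose, 3 adjusted over the list alone, and 0 fell (median 0.42, camera adjusted p = 0.0061, 0.235 with an estimated correlation). It was Taldo1, transaldolase of the pentose phosphate pathway, at 72.6 ± 9.97 and 183 ± 11.3 CPM (1.34, edgeR adjusted p = 0.012). In the iron and heme list 2 of 20 rose and 0 fell, 7 and 1 adjusted over the list alone (median 0.38, camera adjusted p = 0.0003, 0.235 with an estimated correlation). Slc40a1, the iron exporter ferroportin, went from 18.5 ± 4.55 to 93.1 ± 31.9 CPM (2.34, edgeR adjusted p = 0.0096). Ftl1, ferritin light chain, went from 171 ± 23.2 to 390 ± 45.5 CPM (1.19, adjusted p = 0.025). In the list of construct genes and NRF2 partners 1 of 13 members rose, Pax8 itself, 4 adjusted over the list alone (median 0.04, camera adjusted p = 0.0204, 0.235 with an estimated correlation). That list's call ended with the replicate block (adjusted p = 0.0802), without empty vector replicate 1 (0.201) and without fusion replicate 1, 2 or 3 (0.128, 0.224 and 0.15). Its median lay between -0.03 and 0.18 when 1 library was left out, lowest without empty vector replicate 2 and highest without empty vector replicate 1. With the replicate block 8 members rose and 0 fell in the NADPH list, 9 and 3 in the iron and heme list and 5 and 0 in the list of construct genes. The 3 iron and heme members that fell were Cpox, Ppox and Steap3, named, like Prdx4 and Gpx8, after their values were seen. Leaving out 1 library ended the calls of Cat, Gclc, Taldo1 and Ftl1 in 1, 3, 2 and 5 of 6 fits (highest adjusted p 0.0541, 0.0909, 0.0669 and 0.109).

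The largest rises were in genes with almost no empty vector reads. Chl1, a neural cell adhesion molecule (chromosome 6:103510586-103750211), had 3 reads over the empty vector libraries and 186 ± 75.3 CPM with the fusion, a ratio of 10610 with a 95% counting interval of 3630 to 51454 (edgeR adjusted p = 0.00067). Gsta2, a glutathione transferase (chromosome 9:78331018-78355788), had 0 empty vector reads and 40.5 ± 14.4 CPM with the fusion, at least 1954-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 0.0008). By the same floor Cpn1, the catalytic subunit of carboxypeptidase N, was at least 855-fold higher at 17.9 ± 7.32 CPM (adjusted p = 0.0017), and Sall3, a zinc finger transcription factor, at least 316-fold at 5.28 ± 3.3 CPM (0.012). Il1f9, an interleukin 1 family cytokine, was at least 277-fold higher at 5.73 ± 2.07 CPM (0.0026), and Gsta1 at least 242-fold at 4.95 ± 1.42 CPM (0.0021). Gpbar1, a bile acid receptor, lay at 6.13 ± 0.85 CPM with the fusion against 1 empty vector read, a ratio of 933 (interval 167 to 36894, edgeR adjusted p = 0.0007). Pgm5, a phosphoglucomutase-like protein of cell junctions, lay at 12.4 ± 14 CPM against 1 read, a ratio of 2325 (interval 417 to 91889, adjusted p = 0.015). Its call ended in 1 of the 6 fits that left out a library (adjusted p = 0.101). Gsta1 and Gsta2 are close paralogs, so the split of reads between them is uncertain.

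Of the 8 largest falls that the rule took, 6 were in Ncam2, Adcy8, Adcyap1r1, Pcdh20, Cdh10 and Itih5, which were not tested as a group. Ncam2, a neural cell adhesion molecule, went from 10.1 ± 5.61 to 0.745 ± 0.218 CPM (log2 fold change -3.77, SE 0.56, edgeR adjusted p = 0.014). Adcy8, an adenylyl cyclase, went from 17.8 ± 5.83 to 1.83 ± 0.89 CPM (-3.31, SE 0.44, 0.0086). Adcyap1r1, the receptor of the peptide PACAP, went from 48.5 ± 16.1 to 6.61 ± 2.55 CPM (-2.88, SE 0.37, 0.0075). Pcdh20, a protocadherin, went from 24.2 ± 12.1 to 3.04 ± 1.37 CPM (-2.99, adjusted p = 0.027). Cdh10, a cadherin, went from 10.3 ± 1.81 to 1.48 ± 1.12 CPM (-2.83, adjusted p = 0.032). Itih5, a hyaluronan-binding matrix protein, went from 6.23 ± 4 to 0.779 ± 0.365 CPM (-3.03, adjusted p = 0.033). Not every faller lay high in the WT library: it held 1.62 CPM of Ncam2, 3.57 of Adcy8 and 0.501 of Itih5, against 16.2 of Pcdh20 and 100 of Adcyap1r1. Leaving out 1 library ended the calls of Ncam2, Itih5, Pcdh20 and Cdh10 in 3, 3, 4 and 5 of 6 fits (highest adjusted p 0.068, 0.146, 0.0864 and 0.118).

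The other falls among the 8 were neighbours on chromosome 9, and that stretch was looked at only after its values were seen. Cep126, a centrosome and cilium protein (chromosome 9:8076461-8134294), went from 61.8 ± 9.98 to 9.64 ± 0.897 CPM (log2 fold change -2.68, SE 0.21, edgeR adjusted p = 0.001), with 17.3 CPM in the WT library. Cfap300, a cilium protein (chromosome 9:8021672-8042823), went from 214 ± 140 to 34.4 ± 8.92 CPM (-2.63, SE 0.46, adjusted p = 0.029), with 92.8 CPM in the WT library. Its call ended in 3 fits that left out a library (highest adjusted p 0.114). Over chromosome 9:5308828-8134294, from Casp4 to Cep126, 14 of 16 tested genes had lower fitted values with the fusion and 5 of them passed, 10 with the replicate block, with a median log2 fold change of -2.0 over the 16. The others that passed were Dync2h1, a cilium motor (-2.43, edgeR adjusted p = 0.0052), Tmem123 (-2.27, 0.011) and Yap1, a transcriptional coactivator of the Hippo pathway (-1.80, 0.0096), while Mmp13, a collagenase in the same stretch, rose (3.16, 0.022). The region's median level relative to the tested libraries was 0.0448, 0.792 and 1.77 in empty vector replicates 1, 2 and 3, -1.11, -0.815 and -0.67 in the fusion replicates and 0.189 in the WT library, on a log2(CPM + 0.1) scale.

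**Figure D3:**
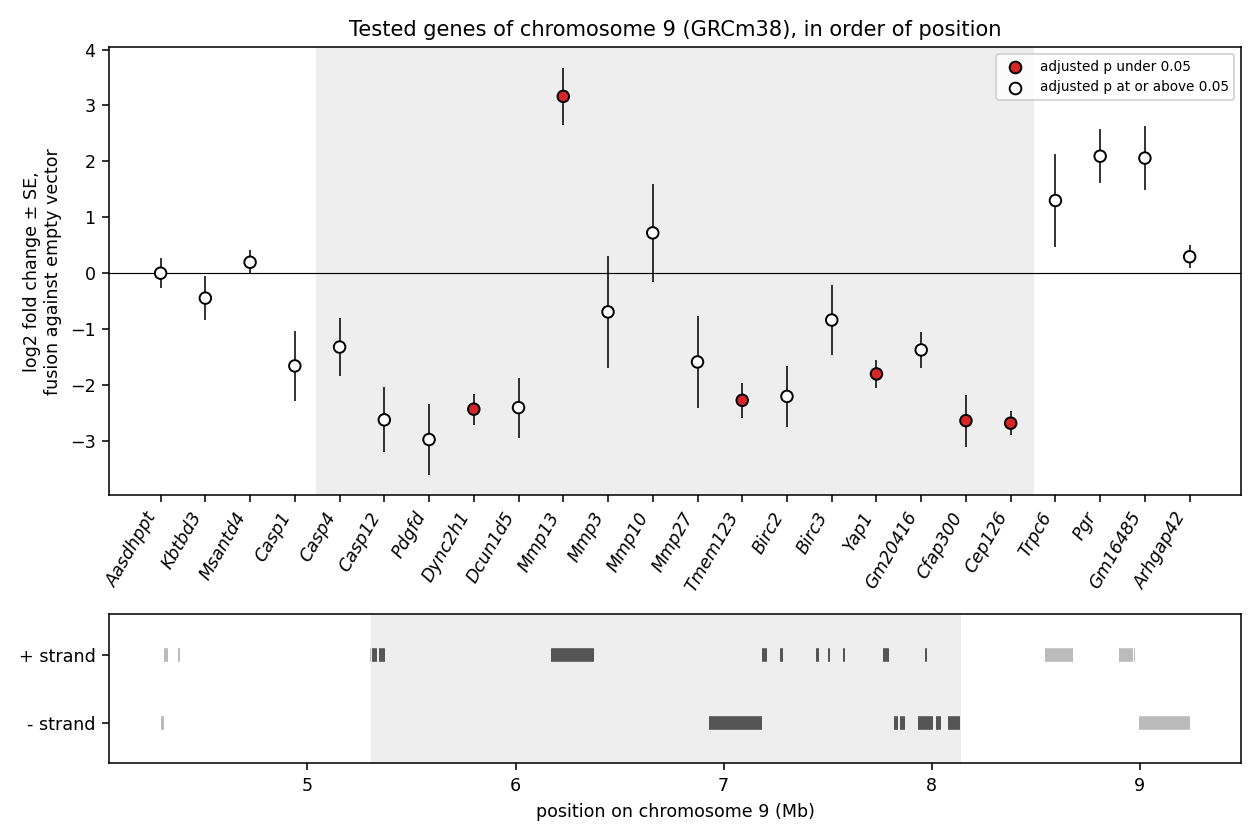
Log2 fold change of fusion against empty vector with its SE (upper panel, filled points for an adjusted p under 0.05) for the tested genes around the shaded stretch from Casp4 to Cep126 on chromosome 9, and their positions in Mb by strand (lower panel). Inside the shaded stretch 14 of 16 genes lie below 0 and Mmp13 lies at 3.16.

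Inflammatory, heat shock and lineage lists shifted upward in the camera test with its preset correlation, each on few called members. In the NF-kB and cytokine list 4 of 21 members rose and 0 fell, 5 and 0 adjusted over the list alone (median 0.18, camera adjusted p = 0.00058, 0.287 with an estimated correlation). They were the neutrophil chemokines Cxcl5 (20.3 ± 3.44 to 135 ± 59.8 CPM, edgeR adjusted p = 0.0096) and Cxcl1 (37.7 ± 5.84 to 104 ± 9.93 CPM, 0.01), the interleukin 33 receptor Il1rl1 and the siderophore-binding protein Lcn2. Il1rl1 went from 472 ± 193 to 1780 ± 437 CPM (0.032) and Lcn2 from 0.159 ± 0.0582 to 0.679 ± 0.0152 CPM (0.046). Leaving out empty vector replicate 1 ended the call of that list (adjusted p = 0.0763). Its median was 0.35 and 0.40 without empty vector replicate 2 or 3 and 0.29 without fusion replicate 3. In the heat shock list 2 of 18 rose and 0 fell, both adjusted over the list alone too (median 0.27, camera adjusted p = 0.0036, 0.161 with an estimated correlation). The small heat shock protein Cryab lay at 13.7 ± 0.664 and 63.7 ± 15.5 CPM (edgeR adjusted p = 0.0033) with 56 CPM in the WT library. Hspb1, of the same family, lay at 4.35 ± 1.33 and 15.4 ± 5.21 CPM (0.047). In the prostate epithelial list 2 of 12 rose and 0 fell, 2 and 0 adjusted over the list alone (median 0.76, 0.48 without fusion replicate 2, camera adjusted p = 0.0023, 0.147 with an estimated correlation). Krt18, a keratin of luminal cells, lay at 0.83 ± 0.543 and 5.92 ± 1.96 CPM (edgeR adjusted p = 0.03). Foxa1, a luminal transcription factor, lay at 0 and 1.54 ± 0.982 CPM, at least 92.8-fold higher (0.024). In the neuroendocrine list 2 of 7 rose and 0 fell, 3 and 0 adjusted over the list alone (median 0.99, camera adjusted p = 0.00099, 0.147 with an estimated correlation). Insm1, a transcription factor, lay at 0 and 0.911 ± 0.14 CPM, at least 47-fold higher (edgeR adjusted p = 0.0052). Scg2, a secretogranin, lay at 0.146 ± 0.0726 and 1.23 ± 0.591 CPM (0.03). Of the prostate epithelial list 12 of 23 members were measured, and of the neuroendocrine list 7 of 11. Foxa1 and Insm1 had 0 empty vector counts and passed the count filter through the fusion libraries only. Their rise thus helped to place them in these medians and camera calls, while members with too few reads in both groups stayed out. The paired fit had 6 members up and 0 down in the NF-kB and cytokine list, 6 and 0 in the heat shock list, 4 and 1, Krt19, named after its value was seen, in the prostate epithelial list, and 3 and 0 in the neuroendocrine list. Leaving out 1 library ended the calls of Il1rl1, Lcn2, Hspb1, Krt18, Foxa1 and Scg2 in 3, 6, 5, 4, 3 and 5 of 6 fits (highest adjusted p 0.114, 0.205, 0.154, 0.138, 0.0765 and 0.116).

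Amino acid stress, interferon, fibroblast and immediate early lists shifted downward in the camera test with its preset correlation. Fry ended the call of each (fry adjusted p = 0.0881, 0.512, 0.149 and 0.149 in that order). In the ATF4 and amino acid list 1 of 30 members fell and 0 rose, 2 and 0 adjusted over the list alone (median -0.41, camera adjusted p = 3.4e-05, 0.253 with an estimated correlation). It was Cth, which makes cysteine from cystathionine, at 143 ± 32.4 and 56.6 ± 10.4 CPM (log2 fold change -1.34, edgeR adjusted p = 0.033) with 66.6 CPM in the WT library. Leaving out 1 library ended its call in 5 of 6 fits (highest adjusted p 0.128). In that list 17 members fell and 2 rose with the replicate block. The interferon list had 0 of 36 members past the threshold, over the list alone too, and a median of -1.25 (camera adjusted p = 5.0e-08, 0.53 with an estimated correlation of 0.794). Its level stood apart in empty vector replicate 2, at 1.69 against -0.345 and 0.153 in replicates 1 and 3, and without that library the median was -0.276. Ifit1, an antiviral protein, lay at 308 ± 163 CPM with empty vector and 163 ± 47 CPM with the fusion (edgeR adjusted p = 0.5, and 0.0451 with the replicate block). The fibroblast list had 0 of 12 past the threshold (median -0.49, camera adjusted p = 0.0061, 0.284 with an estimated correlation). Without fusion replicate 1 the median was -0.32 and the adjusted p 0.0666. Its member Col1a2, a collagen chain, lay at 4867 ± 1369 and 3885 ± 1345 CPM (edgeR adjusted p = 0.91). The immediate early list had 0 of 22 (median -0.31, camera adjusted p = 0.0198, 0.284 with an estimated correlation). Without empty vector replicate 3 the median was -0.16 and the adjusted p 0.141. Its member Egr1 lay at 245 ± 25.4 and 163 ± 46.3 CPM (edgeR adjusted p = 0.42, and 0.0196 with the replicate block). With that block 12 members fell and 0 rose in the interferon list and 4 and 0 in the fibroblast list. In the immediate early list 5 fell and 2 rose. The level of the ATF4 list was -0.151 in the WT library, 0.125 to 0.373 with empty vector and -0.488 to -0.0114 with the fusion. That of the immediate early list was -0.332 in the WT library, -0.00167 to 0.41 with empty vector and -0.223 to -0.0457 with the fusion. In the WT library the interferon (0.51) and fibroblast lists (0.463) lay within the empty vector range.

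**Figure D4:**
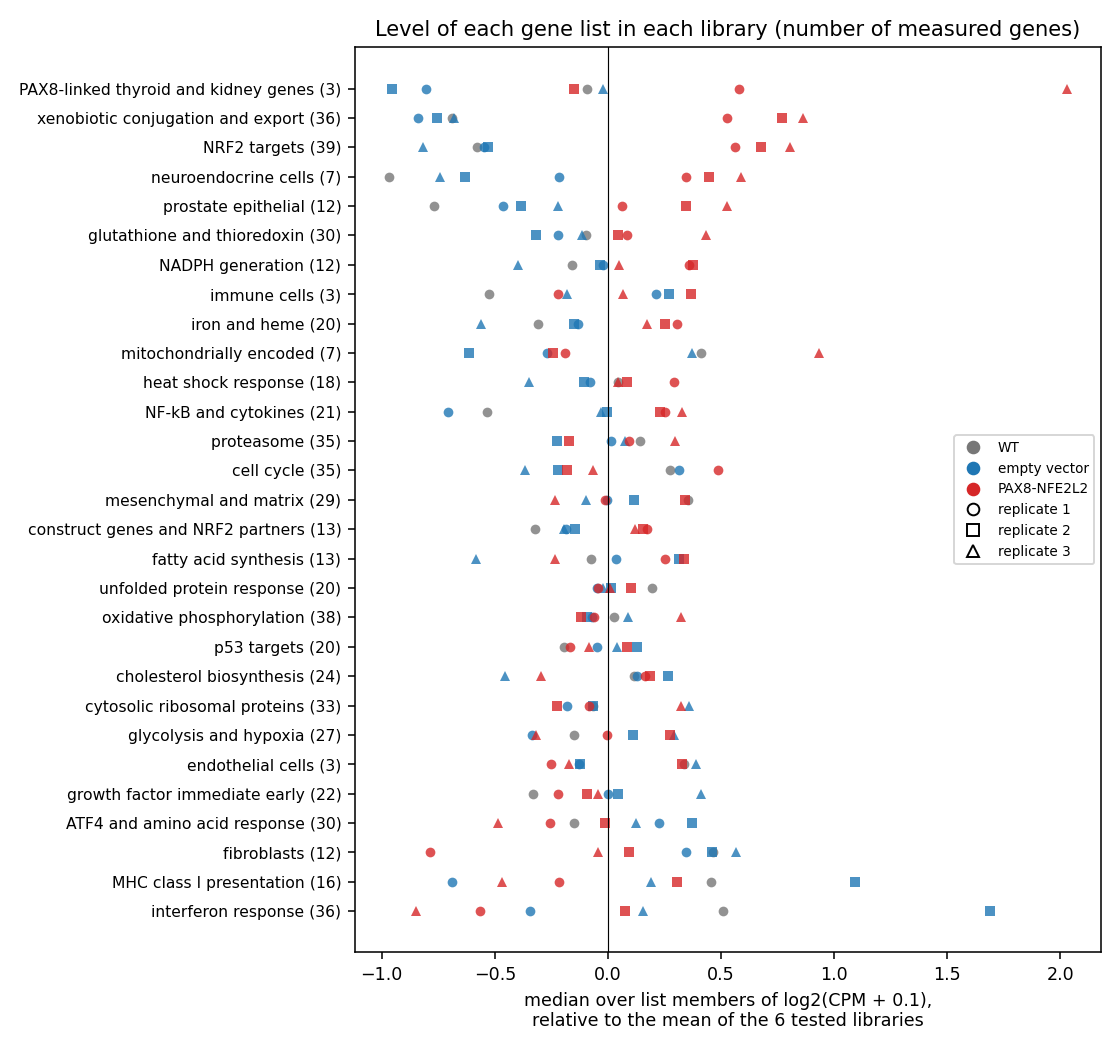
Level of each gene list in each library, as the median over its measured members of log2(CPM + 0.1) relative to the mean of the 6 tested libraries, with the group as colour and the replicate number as symbol. For the NRF2 target list the fusion libraries lie between 0.56 and 0.803 and the empty vector libraries between -0.818 and -0.531, and for the interferon list empty vector replicate 2 lies at 1.69.

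The remaining lists did not pass the camera test. Class I antigen presentation had 0 of 16 members past the gene threshold (median -0.52, adjusted p = 0.107) and passed without empty vector replicate 1 (3.65e-05) and without fusion replicate 2 (0.0157). Its level stood apart in empty vector replicate 2, at 1.09 against -0.688 and 0.191 in replicates 1 and 3. The median was 0.13 without that library, -0.86 without empty vector replicate 1 and -0.93 without fusion replicate 2. Its member Pdia3 lay at 1098 ± 32.2 and 1183 ± 46.1 CPM. In the mesenchymal and matrix list 2 of 29 rose and 0 fell, 2 and 1 adjusted over the list alone (median 0.05, -0.14 without fusion replicate 2 and 0.15 without fusion replicate 3, camera adjusted p = 0.932). They were the proteases Mmp13, at 108 ± 53.4 and 966 ± 401 CPM (edgeR adjusted p = 0.022), and Mmp9, at 0.784 ± 0.434 and 5.56 ± 2.61 CPM (0.042). For the cholesterol list the median of -0.06 and the camera direction, up, differed in sign (adjusted p = 0.659), and the median ran from -0.23 without empty vector replicate 3 to 0.11 without empty vector replicate 2. Of the 17 PAX8-linked thyroid and kidney genes listed only 3 were measured. In that list 1 of 3 measured members rose (median 1.47, camera adjusted p = 0.128, 0.0155 without empty vector replicate 3 and 0.0391 without fusion replicate 2). Its median was 0.20 without fusion replicate 3, 0.94 and 0.93 without empty vector replicate 1 or 2, and 2.37 without empty vector replicate 3. The member that rose was Tg, thyroglobulin, at 0.366 ± 0.132 and 2.32 ± 1.42 CPM with 1.28 CPM in the WT library (edgeR adjusted p = 0.048). Tg overlaps other genes on the opposite strand. Leaving out 1 library ended the calls of Mmp13, Mmp9 and Tg in 2, 5 and 6 of 6 fits (highest adjusted p 0.0737, 0.134 and 0.17). No member passed in the lists of the unfolded protein response (camera adjusted p = 0.983), proteasome (0.358, and 0.0194 without fusion replicate 2), cell cycle (0.908, and 0.0373 without empty vector replicate 1) and p53 targets (0.659). None passed in those of fatty acid synthesis (0.61), glycolysis and hypoxia (0.519, 0.0111 without empty vector replicate 1 and 0.0391 without fusion replicate 2), oxidative phosphorylation (0.969), mitochondrially encoded genes (0.556), ribosomal proteins (0.659), immune cells (0.813) and endothelial cells (0.973). With the replicate block 5 members rose and 0 fell in the proteasome list, 2 and 2 in the unfolded protein response, 2 and 1 in the cell cycle, 3 and 2 among p53 targets, 4 and 1 in fatty acid synthesis and 3 and 4 in the mesenchymal list. With it 1 rose and 0 fell in glycolysis and among mitochondrially encoded genes, 1 and 1 in oxidative phosphorylation, 2 and 0 among PAX8-linked genes, and 0 and 1 among immune cell genes. In the class I, ribosomal protein and endothelial lists none passed. For the oxidative phosphorylation and immune cell lists too the median and the camera direction differed in sign. Of their most abundant members, with empty vector first and the fusion second, Hspa5 lay at 1799 ± 266 and 1753 ± 187 CPM, Top2a at 547 ± 107 and 530.5 ± 84.2, and Plk2 at 325 ± 51.5 and 278 ± 111 CPM. Pkm lay at 1344 ± 207 and 1710 ± 206, Atp5b at 1277 ± 197 and 1222 ± 169, and mt-Co1 at 13397 ± 4794 and 13065 ± 4597 CPM. Rpl8 lay at 1426 ± 31.4 and 1306 ± 131, Cd68 at 1.98 ± 0.667 and 2.6 ± 0.733, and Egfl7 at 4.22 ± 0.989 and 3.59 ± 1.11 CPM. Psmd2 (333 ± 77.5 and 485 ± 85 CPM) and Scd2 (2035 ± 415 and 2862 ± 643 CPM) passed only with the replicate block (edgeR adjusted p = 0.0094 and 0.014), and Pkm only with the block and number 3 left out (0.0061).

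Empty vector was compared with the WT library. Whether the WT cells were untransduced or mock-treated is not given, and their treatment text is the same as for the other libraries, so a difference cannot be assigned to transduction. No gene passed the edgeR quasi-likelihood test, with 0 of 16731 genes at an adjusted p under 0.05 and 746 at an unadjusted p under 0.05. The lone WT library was assumed to vary like the other groups. DESeq2 called 77 genes, 44 higher and 33 lower with empty vector, and edgeR with the replicate block called 20, 6 higher and 14 lower. That block placed the WT library with number 1 by its label. The check of pairing covered only empty vector and fusion libraries. NRF2 targets had a median log2 difference of 0.01, and of -0.06 without empty vector replicate 1 (camera adjusted p = 0.533). Cryab lay at 13.7 CPM with empty vector and 56 CPM in the WT library, a log2 difference of -2.03 (edgeR adjusted p = 0.19). By camera with its preset correlation the ATF4 and amino acid list (median 0.42, adjusted p = 9.7e-07), the immediate early list (0.55, 9.7e-07) and the NF-kB and cytokine list (0.65, 0.00072) were higher with empty vector. The cell cycle (-0.30, 0.0025), mesenchymal and matrix (-0.33, 0.0034), proteasome (-0.19, 0.0185) and heat shock lists (-0.10, 0.0238) were lower, with 0 genes called in any of them. The cell cycle median was -0.45 without empty vector replicate 1, -0.18 without replicate 2 and -0.19 without replicate 3. That of the heat shock list was -0.16 without replicate 1 and that of the proteasome list -0.07 without replicate 2. None of these 7 calls held with an estimated correlation (adjusted p = 0.561, 0.401, 0.736, 0.863, 0.863, 0.863 and 0.561 in that order). Adjusted over the list alone, 1 member was lower in each of the heat shock, fibroblast and immune cell lists. With the replicate block the heat shock (adjusted p = 0.235) and NF-kB lists (0.0549) lost their calls and the cell cycle list had the opposite direction (0.295). With it the lists of the unfolded protein response (0.00133), class I presentation (0.00293), oxidative phosphorylation (0.0344), mitochondrially encoded genes (3.05e-06) and fibroblasts (0.0467) became lower. None of these 5 calls held when the block was combined with an estimated correlation (adjusted p = 0.845 for each). Leaving out empty vector replicate 2 ended the proteasome call (0.193), and leaving out replicate 3 ended the heat shock (0.13) and cell cycle calls (0.0582). The interferon list, with a median of 0.17 and an adjusted p of 0.824, was lower with empty vector when replicate 2 was left out (1.34e-07) and with the replicate block (0.00293), and higher when replicate 1 was left out (0.0175). With an estimated correlation its adjusted p was 0.958, and 0.845 with the block too. The leave-outs were not run with an estimated correlation.

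The lists that did not pass in this comparison had camera adjusted p-values of 0.0535 for the unfolded protein response, 0.148 for mitochondrially encoded genes, 0.17 for cholesterol, 0.171 for glycolysis and hypoxia, and 0.284 for glutathione and thioredoxin and for fibroblasts. They were 0.357 for p53 targets and 0.377 for class I presentation. They were 0.45 for conjugation and export, for iron and heme and for PAX8-linked genes, 0.464 for ribosomal proteins, 0.489 for prostate epithelial genes, and 0.533 for construct genes, NADPH and oxidative phosphorylation. The highest were 0.758 for neuroendocrine genes, 0.799 for immune and endothelial cells and 0.824 for fatty acid synthesis. Without empty vector replicate 1 the glycolysis list passed (0.00166), without replicate 2 the lists of the unfolded protein response (0.0411), class I presentation (2.98e-05) and cholesterol (0.00346), and without replicate 3 the mitochondrially encoded genes (0.00681).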

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

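The replicate block with a replicate number left out, or combined with another list test, was chosen after the data were seen. Fusion against empty vector gave 341 genes (282 higher, 59 lower, 336 at least 2-fold). Counts stayed within 1.5 times of these with RLE (346), upper quartile (331) and library size scaling (338), a 1 CPM filter (273), limma-voom (372), all 7 libraries (342), 1 lane per library (316), thinning (317) and without number 3 (329). With no filter 530 genes passed (133 lower, 524 at least 2-fold) of 27087 tested. DESeq2 called 922 (622 higher, 300 lower, 776 at least 2-fold), among them all 341, so 67.5% were higher, against 82.7%. The paired fit with the replicate block called 2196 (1276 higher, 920 lower, 863 at least 2-fold), 58.1% higher. A threshold of 0.01 left 119 (110 higher, 9 lower, all 119 at least 2-fold). Leaving out number 1 gave 36 genes (34 higher, 2 lower, 36 at least 2-fold) and leaving out number 2 gave 4 (4 higher, 0 lower, 4 at least 2-fold). The replicate block gave 1537 without number 1 (836 higher, 701 lower, 755 at least 2-fold), 409 without number 2 (122 lower) and 3200 without number 3 (1842 higher, 1358 lower, 1252 at least 2-fold). Leaving out 1 library gave 133 to 384 genes, with 123 to 309 higher, 10 to 75 lower and 133 to 384 at least 2-fold; the lowest was without empty vector replicate 2. None of the 43 named genes that passed changed direction in these fits, while fitted values of 6 of the 17 others changed sign. In every called gene all fusion libraries lay on one side of all empty vector libraries. Leaving libraries out could therefore hardly turn the direction of the 43. Of the 43, 22 kept the call whichever library was left out and 40 under every scaling; Hspb1, Lcn2 and Tg lost it with upper quartile and library size scaling. The replicate block ended no named gene's call and added Keap1, Psmd2, Ifit1, Scd2 and Egr1, and DESeq2 added Keap1. Among lists the block ended only the call of construct genes and NRF2 partners (0.0802). The NRF2 target list had adjusted p-values from 2.11e-70 to 0.262 over its alternatives, and only the replicate block with an estimated correlation (0.262) ended its call, as it did for the other lists that passed. Fry ended 5 list calls, those of the ATF4 and amino acid, interferon, NF-kB and cytokine, fibroblast and immediate early lists. The cause of these differences was not tested.

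Empty vector against WT gave 0 genes in edgeR, and 0 with RLE, library size scaling, a 1 CPM filter and without each empty vector library (0 higher, 0 lower). No filter gave 15 (2 higher, 13 lower), DESeq2 77 (44 higher, 33 lower), the 4 WT and empty vector libraries alone 3 (0 higher, 3 lower) and the replicate block 20 (6 higher, 14 lower). Scaling by library size moved the median of all genes from 0.012 to 0.121 and changed no list call, while fry ended all 7. The interferon list turned from higher to lower with the replicate block (camera adjusted p = 0.00293) and without empty vector replicate 2 (1.34e-07). Its adjusted p ran from 1.34e-07 to 0.323 without 1 empty vector library and up to 0.981 over all alternatives. Its level was 0.51 in the WT library and -0.345, 1.69 and 0.153 in empty vector replicates 1, 2 and 3. Only replicate 2 lay above the WT library, and the block sets the WT library beside number 1. The cell cycle list turned from lower to higher with the replicate block (0.295), also with an estimated correlation (0.845) or fry (0.371), over alternatives from 1.17e-06 to 0.863. Beyond these levels no cause was tested. Depth limits genes near 0, where 3 counts correspond to 0.0503 to 0.114 CPM.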

Other observations

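The tests of chromosome 9 correlation and of other splits were chosen after the results were seen. The prediction for YAP1 targets was written before its result, but the bootstrap SE of their median was not part of it. The 341 genes called between fusion and empty vector were set against the other ways to split the 6 libraries: of 10 splits only 1, the real one, gave as many, and the highest other gave 0. Among the 4 splits that part all 3 pairs, the real one gave 2196 genes with the replicate block and the highest other 0. The others mix fusion and empty vector libraries on each side, and 10 splits are too few for a share under 0.05.

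Genes from Casp4 to Cep126 on chromosome 9 were low with the fusion as a block, relative to empty vector. Their median log2 fold change of -2.0 was reached by 2 of 16344 runs of 16 adjacent tested genes. The other was shifted by 1 gene, and the next lowest run elsewhere had -0.808. The ends of the stretch and the run length of 16 were chosen from these values. Its rank therefore describes the stretch and is no test of it. Of the genes next to its ends, Casp1 had a log2 fold change of -1.66 and Trpc6 of 1.30. Empty vector in turn had higher fitted values than the WT library for all 16 genes, Mmp13 included. These log2 differences ran from 0.34 to 1.94, and none passed the threshold. The region's median level was 0.189 in the WT library, 0.0448 to 1.77 with empty vector and -1.11 to -0.67 with the fusion. One hypothesis was that lower Yap1 RNA goes on to lower the targets of YAP1. Of 22 measured targets none was called and 13 lay above 0, and their median log2 fold change was 0.0402 (bootstrap SE 0.104). Camera with a preset correlation gave the direction up without passing 0.05. By the prediction written before the result, a median at or above 0 counted against the hypothesis, and the median lay there. Members went both ways and the median lies within its bootstrap SE of 0, so these values do not settle the hypothesis. A candidate explanation is that the cell populations differ in DNA copy number of the region. Within groups too its genes deviated together, with a mean pairwise correlation of 0.675 at the 99.8 percentile of all runs. The region's level spread mainly among the empty vector libraries, at 0.0448, 0.792 and 1.77 in replicates 1, 2 and 3. The fusion libraries spanned only -1.11 to -0.67. Empty vector replicate 3 came from another sequencing lane than replicates 1 and 2, and the correlation was not computed without it. Shared regulation of neighbouring genes could give the same correlation, RNA counts do not measure DNA copy number, and Mmp13 in the same stretch rose. An effect of the fusion on the region stays open, as untested.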
